A study of Mus musculus with 12 samples.

How the data were processed

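RNA was sequenced from primary mouse hepatocytes in 12 libraries, made from total RNA with a TruSeq kit. They formed 4 groups of 3: AEG-1-WT (wild type), untreated or given CP775146 for 24 h, and the knock-in AEG-1-L24K/L25H under the same conditions. The values are raw read counts per gene, 1 file per library, and per the file headers they were made by the authors with featureCounts 1.6.2 over exons summed by gene, without strand or multi-mapping options, on Subread alignments to mm10 with Ensembl annotation release 83 (GRCm38). The processing notes of the authors name featureCounts 1.4.6-p4 in its place, together with FastQC 0.11.2, cutadapt 1.9 and edgeR 3.18.1. No normalization was applied before deposit. The files list 46983 genes, of which 46488 IDs were matched to a symbol and 495 were not, and 46466 of the matched IDs overlap the same locus in the annotation that gave the symbols. The 37 mitochondrial genes hold 0 counts in every library. How reads of the mitochondrial chromosome were handled is not stated, so these zeros are not read as a lack of expression. The printed dose of the agonist has an impossible unit and is not given.

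Counts were filtered with filterByExpr (minimum count 10, minimum total 15), which left 15664 of the 27924 genes with any count and at least 99.94% of the counts of each library. They were scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit, robust) with 1 term per group over all 12 libraries. Each of 5 contrasts was tested with glmQLFTest: genotype without treatment, CP775146 in each genotype, genotype with treatment, and the interaction. A change was called at a Benjamini-Hochberg adjusted p below 0.05. CPM are given on TMM-scaled library sizes.

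Total counts were 26956032 to 34885451 per library, and a count of 3 equals 0.086 to 0.111 CPM. The coefficient of biological variation was 5.1% and 5.33% in untreated and treated wild type and 2.59% and 2.63% in untreated and treated knock-in. In a test on simulated data, 50 of 15664 genes were changed per fold. For CP775146 in wild type, 56% of 1.25-fold, 84% of 2-fold and 96% of 3-fold changes were recovered, with 10 of 15464 unchanged genes called. For the interaction the shares were 42%, 68% and 94%, with 8 of 15464 called. For the genotype effect without treatment, 56%, 88% and 94% were recovered, with 13 unchanged genes called. Of 20 simulated lists of 25 genes shifted by 0.3 log2, 20 were called by camera, and of 200 without a shift, 0. The simulated genes were drawn independently, so this test does not cover lists whose members vary together. All simulated groups also shared the same spread for a gene, and few genes were changed, unlike in the data. The test therefore does not show how many false calls arise where wild type varies more than the knock-in. The correlation estimated between members was 0.829 for interferon-stimulated genes, 0.204 for PPAR-alpha targets and 0.018 for cell-cycle genes.

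Gene lists were written before the data were examined, as were the tests, the rule for naming genes and the alternatives except where stated. The 35 lists covered PPAR-alpha targets, mitochondrial and peroxisomal beta-oxidation, microsomal omega-oxidation, ketone body, fatty acid and triglyceride, and cholesterol synthesis, LXR, CAR and PXR, retinoic acid receptor, NRF2, p53 and Wnt targets, bile acid genes, NF-κB and inflammatory, acute-phase and interferon-stimulated genes, differentiated hepatocyte and dedifferentiation genes, the cell cycle, pericentral and periportal genes, stress responses, and gluconeogenesis and glycolysis. They also covered markers of macrophages, endothelial cells, stellate cells, cholangiocytes, neutrophils and lymphocytes, and mesothelium, and erythroid, mitochondrially encoded, Y-linked and X-inactivation, male-biased and female-biased genes. Each of the 30 lists with at least 2 tested members was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation of 0.01, and again with the correlation estimated from the data. For each, the calls among members were counted over all genes and after adjustment over the list alone. Named genes were the 10 largest rises and 10 largest falls of each contrast with a mean of at least 1 CPM, up to 4 members of each list with the smallest adjusted p, or the 2 with the highest CPM where none passed, and Mtdh, nuclear receptor genes and classical PPAR-alpha targets. The largest rises and falls left out genes with a Gm-number, Rik, clone or pseudogene name. For them, in contrasts of 2 groups, the libraries of the groups also had to be separated without overlap. List members and the always named genes did not have to meet these conditions.

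Alternatives were RLE and total-count scaling, DESeq2 1.42.0, limma voom with sample weights, no filter, a filter of 5 CPM in 3 libraries, fits of the compared groups alone, a 2-fold minimum, the replicate number as a block, across all groups or within each genotype, camera with an estimated correlation, and leaving out each library. Thinning all libraries to the smallest total was chosen after seeing the data. No library was left out of the main comparisons. Some genes that the naming rule selected are not reported. Genotype and hepatocyte preparation are confounded, and the gene counts do not show the coding change.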

Results

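RNA was measured in primary mouse hepatocytes from AEG-1-WT mice (wild type) and AEG-1-L24K/L25H mice (the knock-in), which carry 2 amino acid changes in AEG-1, the protein that the gene Mtdh encodes. Cultures of each genotype were left untreated or given CP775146, an agonist of the fatty acid receptor PPAR-alpha, for 24 h. This gave 4 groups of 3 libraries each, 12 in all. Total counts ran from 26956032 to 34885451 per library. Group means were 27.5 ± 0.52 M in untreated wild type, 31.2 ± 1.65 M in treated wild type, 31.2 ± 1.7 M in untreated knock-in and 32.6 ± 2.05 M in treated knock-in (SD, n = 3). Of 46983 genes in the files, 15664 were tested. Levels are CPM (counts scaled to library size) on the TMM scale, given as mean ± SD over the 3 libraries of a group, and fold changes are log2 ± SE. The adjusted p of a gene is from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, called the edgeR adjusted p. That of a gene list is from the camera test of limma with the same adjustment. At the lowest and highest totals, a count of 3 corresponds to 0.111 and 0.086 CPM, and such floors cover counting error only. The labels do not say that the 3 libraries of a group came from separate animals or separate cultures, so the p-values may measure technical spread only. Genotype cannot be told apart from the animals and the hepatocyte preparation of each genotype. The sample titles call the controls untreated and name no vehicle, so effects of CP775146 cannot be told apart from those of a vehicle.

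Mtdh, the edited gene (ENSMUSG00000022255, chromosome 15, 34082694 to 34142386, GRCm38/mm10), was expressed in every library. It stood at 166 ± 8.47 CPM in untreated and 181 ± 4.32 CPM in treated wild type, and at 173 ± 1.98 CPM in untreated and 193 ± 3.72 CPM in treated knock-in. Single libraries ran from 157.4 to 196.8 CPM. The genotypes differed by 0.06 ± 0.04 log2 without treatment (edgeR adjusted p = 0.262). Gene-level counts cannot show the amino acid changes, so they do not check the genotype labels. Ppara, which encodes the receptor that the agonist binds (ENSMUSG00000022383, chromosome 15, 85734983 to 85802819), was lower in the knock-in, at 73.3 ± 2.32 against 87.6 ± 1.17 CPM untreated (−0.26 ± 0.05 log2, edgeR adjusted p = 3.84e-05).

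The first comparison asked what the knock-in changed in untreated hepatocytes. Transcripts of DNA replication and mitosis genes were higher in the knock-in, among them Mki67, a proliferation marker, which rose from 2.53 ± 0.07 to 11.4 ± 0.4 CPM (2.18 ± 0.11 log2). Cxcl1, a chemokine gene that draws neutrophils, rose from 5.33 ± 1.18 to 22.1 ± 2.13 CPM. The albumin gene Alb took 7.25% to 7.73% of counts in the knock-in libraries and 10.06% to 10.26% in wild type. Cyp2e1, a pericentral cytochrome P450, fell from 527 ± 6.88 to 156 ± 7.22 CPM. Cd36, which encodes a fatty acid uptake receptor and is a PPAR-alpha target (ENSMUSG00000002944, chromosome 5, 17781690 to 17888801), rose 7.68-fold, from 73.3 ± 10.5 to 563 ± 5.71 CPM (2.94 ± 0.08 log2, edgeR adjusted p = 1.74e-12).

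Among genes that met the naming rule, with a mean of at least 1 CPM, the largest rises also included Spink1, a trypsin inhibitor gene (3 ± 0.24 log2), Flnc, which encodes filamin C (2.64 ± 0.1), the kinetochore gene Kntc1 (2.57 ± 0.21) and Igf2bp1, which encodes an RNA-binding protein (2.53 ± 0.25). Sult2a1, a hydroxysteroid sulfotransferase gene, rose from 8.51 ± 1.18 to 49.9 ± 1.89 CPM, and its close copy Sult2a2 rose from 3.06 ± 0.58 to 15.3 ± 0.69 CPM. The largest falls by the same mark were in Serpina1e, an alpha-1-antitrypsin gene with near-identical copies, from 518 ± 41.3 to 55.9 ± 2.98 CPM (−3.21 ± 0.05 log2), in A1bg, from 20.4 ± 0.42 to 2.2 ± 0.27 CPM, and in Tmod1, a tropomodulin gene of which 32.6% of the exonic length is shared with Tstd2. Flt1, which encodes a VEGF receptor of endothelial cells, fell from 72.7 ± 6 to 13.9 ± 1.21 CPM, and Angptl2 from 42 ± 3.13 to 10 ± 0.67 CPM. These falls had edgeR adjusted p-values between 1.51e-25 for Serpina1e and 5.37e-11 for Tmod1.

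Of 30 tested cell-cycle genes, 28 rose and 1 fell, both over all genes and adjusted over the list alone (median 1.39 log2, limma camera adjusted p = 9.84e-15). The replication helicase genes Mcm5 (1.51 ± 0.07 log2) and Mcm4 (1.38 ± 0.08) were among them. The exception was Rrm2, a ribonucleotide reductase gene, at 59.2 CPM in wild type and 34.5 CPM in the knock-in. NF-κB and inflammatory genes rose in 17 of 24 cases and fell in 1, with 19 rises and 1 fall adjusted over the list alone (median 0.3, limma camera adjusted p = 9.4e-07). Ccl2, a monocyte chemokine gene, rose from 16.9 ± 0.28 to 47.2 ± 1.47 CPM, and Icam1, an adhesion molecule gene, from 27.3 ± 1.81 to 55.3 ± 0.61 CPM. Genes that rise as hepatocytes lose identity in culture rose in 16 of 26 cases and fell in 6, by either adjustment, and also adjusted over the list alone (median 0.59, limma camera adjusted p = 1.99e-06). Anxa3, an annexin gene, rose from 124 ± 2.26 to 360 ± 5.67 CPM, and Ankrd1, a target of the Hippo pathway, from 10.4 ± 1.51 to 41.7 ± 0.77 CPM. Cholangiocyte markers rose in 8 of 9 cases with no fall, also adjusted over the list alone (median 0.58, limma camera adjusted p = 1.24e-06). They included Krt19, a bile duct keratin gene, from 3.39 ± 0.15 to 9.21 ± 0.39 CPM, and Spp1, which encodes osteopontin, from 5.54 ± 1.3 to 17.1 ± 1.24 CPM. This list shares 4 members with the dedifferentiation list.

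PPAR-alpha targets rose in 36 of 51 cases and fell in 10, with the same counts adjusted over the list alone (median 0.35, limma camera adjusted p = 3.59e-08; adjusted p = 0.17 with an estimated correlation). Acot1, an acyl-CoA thioesterase gene, rose from 3.79 ± 0.65 to 14.5 ± 0.26 CPM, and Plin2, which encodes a lipid droplet coat protein, from 452 ± 15.6 to 789 ± 13.7 CPM. In contrast, Cyp4a10, a fatty acid omega-hydroxylase gene, fell from 63 ± 7.28 to 30.3 ± 0.56 CPM. Mitochondrial beta-oxidation genes rose in 14 of 21 cases and fell in 3, with 15 rises and 3 falls adjusted over the list alone (median 0.2, limma camera adjusted p = 0.000128; adjusted p = 0.35 with an estimated correlation), led by Cpt1a, the carnitine palmitoyltransferase gene of the liver (0.64 ± 0.05 log2). Peroxisomal beta-oxidation genes rose in 12 of 23 cases and fell in 4, as they did adjusted over the list alone (median 0.18, limma camera adjusted p = 0.0129; adjusted p = 0.271 with an estimated correlation). Cholesterol synthesis genes rose in 11 of 25 cases and fell in 3, with 12 rises adjusted over the list alone (median 0.1, limma camera adjusted p = 0.0312; adjusted p = 0.35 with an estimated correlation). NRF2 targets, which act against oxidative stress, rose in 10 of 20 cases and fell in 5, also adjusted over the list alone (median 0.11, limma camera adjusted p = 0.0218; adjusted p = 0.409 with an estimated correlation), with Abcc4, an efflux pump gene, at 31.8 ± 1.71 and 73.7 ± 4.41 CPM.

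Acute-phase genes fell in 19 of 27 cases and rose in 4, with 5 rises adjusted over the list alone (median −0.39, limma camera adjusted p = 2.5e-07; adjusted p = 0.057 with an estimated correlation). Serpina3n, a protease inhibitor gene, fell from 1978 ± 168 to 1078 ± 11.4 CPM and Crp, which encodes C-reactive protein, from 347 ± 12.4 to 229 ± 1.9 CPM. Differentiated hepatocyte genes fell in 18 of 31 cases and rose in 7, with 19 falls adjusted over the list alone (median −0.16, limma camera adjusted p = 0.000812; adjusted p = 0.17 with an estimated correlation), among them Ahsg, which encodes fetuin-A, from 7414 ± 194 to 4162 ± 18.7 CPM. Genes of gluconeogenesis and glycolysis fell in 13 of 20 cases and rose in 3, as they did adjusted over the list alone (median −0.28, limma camera adjusted p = 0.00147), with Pfkl, the liver phosphofructokinase gene, at −0.52 ± 0.04 log2. Periportal genes fell in 10 of 17 cases and rose in 2, with 3 rises adjusted over the list alone (median −0.3, limma camera adjusted p = 0.0056; adjusted p = 0.115 with an estimated correlation). Targets of p53 fell in 9 of 17 cases and rose in 2, with 3 rises adjusted over the list alone (median −0.15, limma camera adjusted p = 0.0142; adjusted p = 0.0757 with an estimated correlation). Retinoic acid receptor targets fell in 5 of 8 cases, with 1 rise adjusted over the list alone (median −0.23, limma camera adjusted p = 0.0323; adjusted p = 0.148 with an estimated correlation), led by Tgm2, a transglutaminase gene, from 3613 ± 237 to 1861 ± 53.5 CPM. In all, 2884 genes rose and 2918 fell, 37% of those tested, and 471 and 283 of them changed at least 2-fold. Scaling by total counts alone gave 5024 rises and 1722 falls.

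The second comparison asked how wild-type hepatocytes answered CP775146. The agonist raised each of the 51 tested PPAR-alpha targets. The peroxisomal bifunctional enzyme gene Ehhadh (ENSMUSG00000022853, chromosome 16, 21761287 to 21787844) went from 52.5 ± 2.67 to 3898 ± 93.5 CPM (6.21 ± 0.05 log2, edgeR adjusted p = 7.03e-37). Pdk4, which restrains glucose oxidation, went from 21.3 ± 1.42 to 639 ± 27.7 CPM. Fatty acid oxidation in mitochondria and peroxisomes, ketone body synthesis and cholesterol synthesis rose as groups. Tat, which encodes tyrosine aminotransferase, fell from 134 ± 7.98 to 23.7 ± 4.25 CPM. Cell-cycle genes and Cps1, the entry enzyme gene of the urea cycle, fell as well.

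Large rises outside the lists were in Fbp2, the muscle-type fructose bisphosphatase gene (ENSMUSG00000021456, chromosome 13, 62836884 to 62858400), from 1.85 ± 0.16 to 167 ± 8.91 CPM, and in Rapgef5, a Rap exchange factor gene (5.61 ± 0.13 log2). Rab15, a vesicle traffic gene (5.58 ± 0.15), and Cbfa2t3, a transcriptional corepressor gene (5.35 ± 0.19), followed, with Chrna2, an acetylcholine receptor gene, at 5.27 ± 0.14. Acot1 rose from 3.79 ± 0.65 to 450 ± 25 CPM and Acot3 from 0.97 ± 0.08 to 68.9 ± 5.72 CPM, and these neighbouring thioesterase genes are similar enough to share reads. Ptger3, a prostaglandin receptor gene, rose to 6.43 ± 0.62 CPM from a total of 4 counts in the 3 untreated libraries. Besides Tat, large falls were in Marcksl1, a membrane and actin regulator gene, from 11.7 ± 1.34 to 1.2 ± 0.13 CPM, and in Mep1a, a meprin protease gene, from 3.24 ± 0.4 to 0.34 ± 0.07 CPM. Tuba1a, a tubulin gene, fell from 43.5 ± 1.73 to 5.12 ± 0.83 CPM, and Tead2, a Hippo pathway transcription factor gene, from 9.06 ± 0.49 to 1.74 ± 0.52 CPM. All of these genes had an edgeR adjusted p of 3.75e-13 or lower, except Tat at 6.23e-11. Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis, was at 0.64 ± 0.19 CPM without and 0.03 ± 0.03 CPM with CP775146, the latter from 3 counts in all.

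PPAR-alpha targets had a median rise of 2.56 log2, with all 51 up by either adjustment, also adjusted over the list alone (limma camera adjusted p = 9.51e-68). Mitochondrial beta-oxidation genes rose in 21 of 21 cases, also adjusted over the list alone (median 1.81, limma camera adjusted p = 3.26e-29), with Hadha, the alpha subunit gene of the trifunctional protein, going from 273 ± 4.45 to 1668 ± 50.5 CPM. Peroxisomal beta-oxidation genes rose in 20 of 23 cases and fell in 1, the same adjusted over the list alone (median 1.44, limma camera adjusted p = 3.82e-22). Acaa1b, a peroxisomal thiolase gene, rose 4.23 ± 0.06 log2. Of each of these oxidation lists, 13 members are also on the PPAR-alpha list. Ketone body genes rose in 4 of 5 cases, as they did adjusted over the list alone (median 1.29, limma camera adjusted p = 7.47e-07). Microsomal omega-oxidation genes rose in 6 of 9 cases and fell in 3, the same adjusted over the list alone (median 1.55, limma camera adjusted p = 0.000143), and Cyp4a14, a fatty acid omega-hydroxylase gene, rose from 145 ± 7.47 to 2742 ± 122 CPM.

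Cholesterol synthesis genes rose in 21 of 25 cases and fell in 2, also adjusted over the list alone (median 0.52, limma camera adjusted p = 3.31e-11), with Hmgcs1, the cytosolic HMG-CoA synthase gene, at 376 ± 19.2 and 734 ± 26.6 CPM. Fatty acid and triglyceride synthesis genes rose in 16 of 24 cases and fell in 4, with 17 rises adjusted over the list alone (median 0.32, limma camera adjusted p = 3.03e-06). The stearoyl-CoA desaturase gene Scd1 rose from 3071 ± 175 to 9577 ± 284 CPM. LXR targets rose in 9 of 14 cases and fell in 3, the same adjusted over the list alone (median 0.42, limma camera adjusted p = 0.0107; adjusted p = 0.0696 with an estimated correlation). NRF2 targets rose in 11 of 20 cases and fell in 4, with 5 falls adjusted over the list alone (median 0.31, limma camera adjusted p = 0.000871; adjusted p = 0.275 with an estimated correlation), led by Cbr3, a carbonyl reductase gene, at 8.04 ± 0.52 and 33.9 ± 3.38 CPM. Genes of gluconeogenesis and glycolysis rose in 12 of 20 cases and fell in 4, also adjusted over the list alone (median 0.25, limma camera adjusted p = 0.0119). G6pc, the glucose-6-phosphatase gene, rose from 7.32 ± 1.02 to 30.6 ± 1.62 CPM, whereas Slc2a2, which encodes the glucose transporter GLUT2, fell from 368 ± 9.24 to 198 ± 10.6 CPM. Dedifferentiation genes rose in 15 of 26 cases and fell in 7, as they did adjusted over the list alone (median 0.23, limma camera adjusted p = 0.0136; adjusted p = 0.0585 with an estimated correlation). Cell-cycle genes fell in 20 of 30 cases with no rise, also adjusted over the list alone (median −0.5, limma camera adjusted p = 7.16e-05), and Mki67 fell from 2.53 ± 0.07 to 0.66 ± 0.23 CPM.

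Differentiated hepatocyte genes went both ways, 9 up and 13 down of 31, with 10 and 13 adjusted over the list alone (median −0.08, limma camera adjusted p = 0.17). Cps1 fell from 1970 ± 145 to 542 ± 20.7 CPM. In this comparison 3553 genes rose and 3496 fell, 45% of those tested, 610 and 405 of them at least 2-fold. With total-count scaling, which put the median of all genes at −0.104 log2 here and at 0.124 log2 in the comparison of treated genotypes, 2358 rose and 5338 fell. Mtdh rose by 0.13 ± 0.04 log2 (edgeR adjusted p = 0.0093), a call that was lost with total-count scaling and without untreated wild-type replicate 2, where the change was 0.09 log2.

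**Figure D1:**
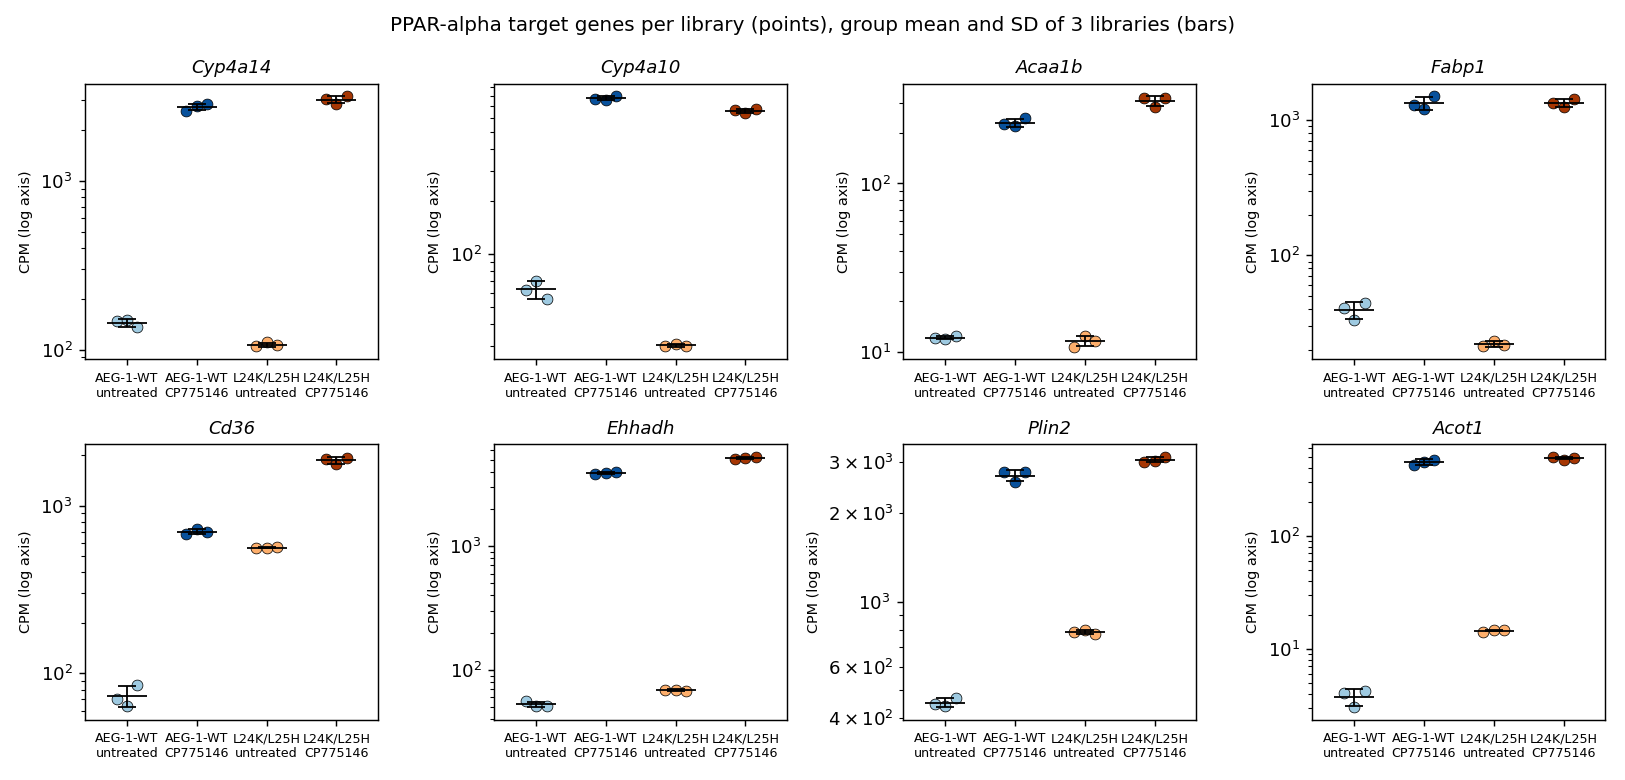
CPM (log axis) of 8 PPAR-alpha target genes in the 12 libraries, by genotype and treatment, with points for libraries and bars for the mean ± SD of 3 libraries. Cd36 stood at 73.3 CPM in untreated wild type and 563 CPM in untreated knock-in, and Cyp4a14 reached 2742 and 3024 CPM with CP775146.

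The third comparison asked the same of knock-in hepatocytes. CP775146 again raised all 51 PPAR-alpha targets, with Ehhadh at 68.7 ± 0.68 CPM before and 5157 ± 90.1 CPM after (6.23 ± 0.05 log2, edgeR adjusted p = 4.73e-37) and Fabp1, the liver fatty acid binding protein gene (ENSMUSG00000054422, chromosome 6, 71199827 to 71205023), at 22.1 ± 0.95 and 1343 ± 88.4 CPM. Oasl1, an oligoadenylate synthetase-like gene, rose from 17.1 ± 2.44 to 42.7 ± 2.13 CPM. Tat fell from 108 ± 1.69 to 23.2 ± 1.16 CPM and Plcl1, a phospholipase C-like gene, from 7.14 ± 0.49 to 1.07 ± 0.08 CPM. Cell-cycle genes fell as a group.

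Mitochondrial beta-oxidation genes rose in 21 of 21 cases (median 1.2, limma camera adjusted p = 2.41e-32) and peroxisomal ones in 21 of 23 with no fall (median 1.22, limma camera adjusted p = 7.89e-28), and both counts were the same adjusted over the list alone. The PPAR-alpha list had a median rise of 2.08 log2, with all 51 also up adjusted over the list alone (limma camera adjusted p = 1.77e-82). Omega-oxidation genes rose in 7 of 9 cases and fell in 2, also adjusted over the list alone (median 1.48, limma camera adjusted p = 1.55e-07). All 5 ketone body genes rose, the same adjusted over the list alone (median 1.06, limma camera adjusted p = 3.9e-08). Fatty acid and triglyceride synthesis genes rose in 19 of 24 cases and fell in 2, also adjusted over the list alone (median 0.43, limma camera adjusted p = 1.77e-12), with Acacb, a mitochondrial acetyl-CoA carboxylase gene, at 63.1 ± 2.13 and 246 ± 3.86 CPM. Cholesterol synthesis genes rose in 21 of 25 cases and fell in 1, also adjusted over the list alone (median 0.32, limma camera adjusted p = 3.02e-12). LXR targets rose in 8 of 14 cases and fell in 3, the same adjusted over the list alone (median 0.24, limma camera adjusted p = 0.00478; adjusted p = 0.0593 with an estimated correlation). Lpcat3, a lysophospholipid acyltransferase gene, rose from 90.5 ± 1.36 to 292 ± 7.37 CPM. NRF2 targets rose in 15 of 20 cases and fell in 3, also adjusted over the list alone (median 0.33, limma camera adjusted p = 8.47e-07; adjusted p = 0.116 with an estimated correlation).

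Interferon-stimulated genes rose in 20 of 24 cases and fell in 1, with 21 rises adjusted over the list alone (median 0.97, limma camera adjusted p = 1.14e-08; adjusted p = 0.279 with an estimated correlation). Without untreated knock-in replicate 3 only 12 rose and 1 fell (median 0.87). Bst2, which tethers virus particles, rose from 167 ± 4.76 to 250 ± 15.8 CPM and Rtp4, a receptor transporter gene, from 14.9 ± 2.03 to 33.4 ± 0.33 CPM, whereas Ifit2, an antiviral gene of the same list, fell from 21.1 ± 1.15 to 13.4 ± 0.29 CPM. Acute-phase genes fell in 15 of 27 cases and rose in 2, also adjusted over the list alone (median −0.3, limma camera adjusted p = 0.000329; adjusted p = 0.116 with an estimated correlation). The fibrinogen beta chain gene Fgb fell from 1253 ± 74.4 to 689 ± 14.1 CPM. Differentiated hepatocyte genes fell in 16 of 31 cases and rose in 6, with 17 falls adjusted over the list alone (median −0.11, limma camera adjusted p = 0.0079; adjusted p = 0.224 with an estimated correlation). Cell-cycle genes fell in 19 of 30 cases with no rise, also adjusted over the list alone (median −0.38, limma camera adjusted p = 8.21e-06), with the helicase gene Mcm2 at −0.48 ± 0.06 log2. Targets of p53 fell in 10 of 17 cases and rose in 5, the same adjusted over the list alone (median −0.14, limma camera adjusted p = 0.0423; adjusted p = 0.103 with an estimated correlation). Stellate cell markers fell in 4 of 16 cases, also adjusted over the list alone (median −0.29, limma camera adjusted p = 0.0361; adjusted p = 0.14 with an estimated correlation), led by Tagln, an actin-binding protein gene, from 26.1 ± 0.6 to 13.4 ± 0.67 CPM.

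Genes of gluconeogenesis and glycolysis rose in 12 of 20 cases and fell in 4, with 5 falls adjusted over the list alone (median 0.36, limma camera adjusted p = 0.00272). Dedifferentiation genes rose in 15 of 26 cases and fell in 4, as they did adjusted over the list alone (median 0.18, limma camera adjusted p = 0.0133; adjusted p = 0.0593 with an estimated correlation). Other large rises were in Sdcbp2, a syntenin gene (5.03 ± 0.17 log2), and in Cbfa2t3 (5.61 ± 0.19). Bex1, an X-linked gene of which 18.8% of the exonic length overlaps Tceal7, fell from 1.83 ± 0.19 to 0.34 ± 0.03 CPM. In all, 2832 genes rose and 2989 fell, 37.2% of those tested, 410 and 241 of them at least 2-fold. Total-count scaling gave 2066 rises and 4352 falls. Mtdh rose by 0.15 ± 0.04 log2 (edgeR adjusted p = 0.00189), and total-count scaling took this call away at 0.09 log2.

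**Figure D2:**
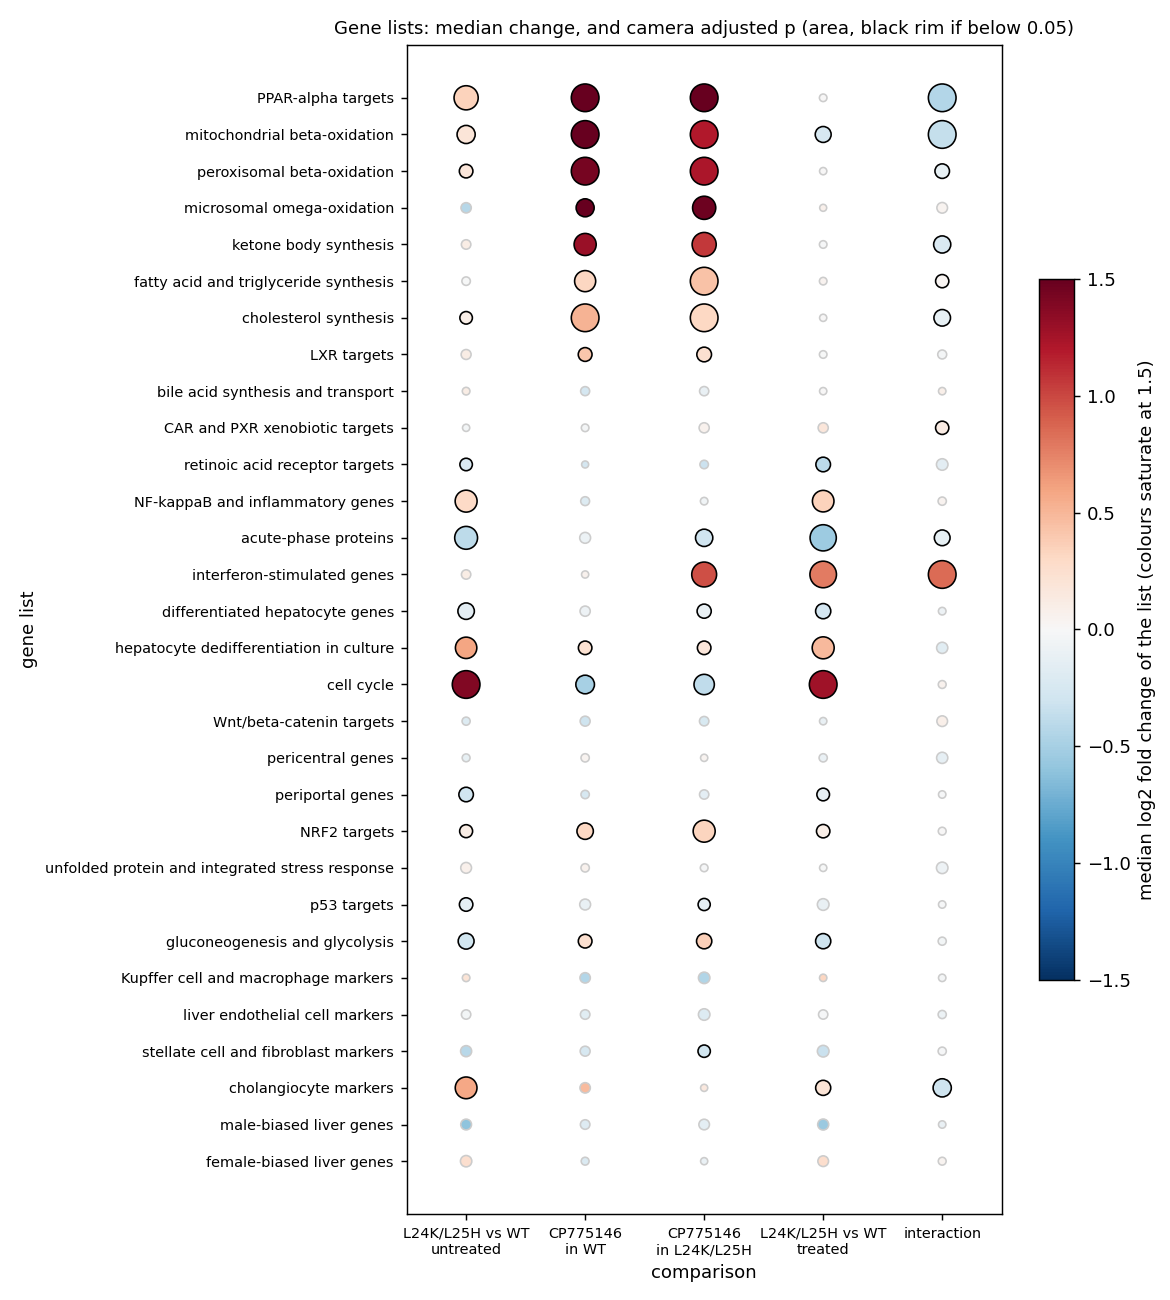
Each dot is 1 of 30 gene lists (vertical axis) in 1 of 5 comparisons (horizontal axis), with the median log2 fold change as colour, which saturates at 1.5, and an area that is larger for a smaller camera adjusted p, black-rimmed below 0.05. Cell-cycle genes had medians of 1.39 and 1.28 between genotypes and −0.5 and −0.38 with CP775146, and PPAR-alpha targets had medians of 2.56 and 2.08 with CP775146.

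The fourth comparison set the treated genotypes side by side. With the agonist present, the knock-in still had more transcripts of proliferation and inflammatory genes. Mki67 stood at 0.66 ± 0.23 CPM in wild type and 8.53 ± 0.58 CPM in the knock-in (3.67 ± 0.15 log2, edgeR adjusted p = 5.74e-18). PPAR-alpha targets leaned to neither side. Serpina1e stayed low in the knock-in, at 58.5 ± 1.52 against 513 ± 13.2 CPM.

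Sult2a1 was again higher in the knock-in (3.08 ± 0.1 log2), as were Fgfbp1, a growth factor binding protein gene (2.9 ± 0.13), and Fgd3, a Cdc42 exchange factor gene, at 14.7 ± 1.78 and 100 ± 1.82 CPM. Elfn1 was lower, at 2.2 ± 0.61 CPM in wild type and 0.08 ± 0.05 CPM in the knock-in, where the 3 libraries held 8 counts. Cyp2s1, a cytochrome P450 gene, fell from 51.6 ± 9.99 to 6.29 ± 1.89 CPM (−3.03 ± 0.23 log2, edgeR adjusted p = 5.15e-06), Flt1 from 39.6 ± 5.25 to 5.63 ± 0.35 CPM and Duox2, an NADPH oxidase gene, from 1.95 ± 0.41 to 0.18 ± 0.08 CPM.

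Cell-cycle genes were higher in 28 of 30 cases and lower in 1, with 29 and 1 adjusted over the list alone (median 1.28, limma camera adjusted p = 1.41e-13). NF-κB and inflammatory genes were higher in 18 of 24 cases and lower in 1, also adjusted over the list alone (median 0.34, limma camera adjusted p = 1.6e-06), with Ccl2 at 7.36 ± 0.73 and 29.7 ± 2.55 CPM. Dedifferentiation genes were higher in 18 of 26 cases and lower in 4, with 20 and 5 adjusted over the list alone (median 0.48, limma camera adjusted p = 8.78e-07). Lgals1, which encodes galectin-1, stood at 12.6 ± 1.75 and 77.9 ± 1.76 CPM. Interferon-stimulated genes were higher in 20 of 24 cases with none lower, and in 22 adjusted over the list alone (median 0.78, limma camera adjusted p = 7.17e-10; adjusted p = 0.353 with an estimated correlation), with Oasl2 at 3.53 ± 1.87 and 15.7 ± 0.76 CPM. Treated wild-type replicate 1 stood apart from the other libraries of its group in this list, and without it 23 were higher (median 1.09). Cholangiocyte markers were higher in 5 of 9 cases, and in 7 adjusted over the list alone (median 0.2, limma camera adjusted p = 0.00326). NRF2 targets were higher in 10 of 20 cases and lower in 5, also adjusted over the list alone (median 0.1, limma camera adjusted p = 0.0151; adjusted p = 0.468 with an estimated correlation), with Slc7a11, the cystine transporter gene, at 18 ± 2.3 and 57.6 ± 4.18 CPM.

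Acute-phase genes were lower in 22 of 27 cases and higher in 4, also adjusted over the list alone (median −0.54, limma camera adjusted p = 1.26e-09). Hpx, which encodes hemopexin, stood at 7996 ± 427 CPM in wild type and 5235 ± 29.6 CPM in the knock-in. Mitochondrial beta-oxidation genes were lower in 13 of 21 cases and higher in 3, with 14 lower adjusted over the list alone (median −0.25, limma camera adjusted p = 0.00141; adjusted p = 0.468 with an estimated correlation). Acaa2, a mitochondrial thiolase gene, differed by −0.53 ± 0.04 log2. Differentiated hepatocyte genes were lower in 16 of 31 cases and higher in 7, with 18 and 8 adjusted over the list alone (median −0.27, limma camera adjusted p = 0.00293; adjusted p = 0.248 with an estimated correlation). Genes of gluconeogenesis and glycolysis were lower in 12 of 20 cases and higher in 5, with 13 lower adjusted over the list alone (median −0.31, limma camera adjusted p = 0.00293). Retinoic acid receptor targets were lower in 5 of 8 cases, also adjusted over the list alone (median −0.4, limma camera adjusted p = 0.00506; adjusted p = 0.0619 with an estimated correlation). Periportal genes were lower in 8 of 17 cases and higher in 2, with 9 lower adjusted over the list alone (median −0.14, limma camera adjusted p = 0.0284; adjusted p = 0.219 with an estimated correlation). Of the 51 PPAR-alpha targets, 19 were higher and 22 lower, or 20 and 23 adjusted over the list alone, with a median of 0 and a camera test pointing down (limma camera adjusted p = 0.76).

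Between the treated genotypes 3218 genes were higher and 3447 lower in the knock-in, 42.5% of those tested, 511 and 400 of them at least 2-fold. Total-count scaling gave 5950 higher and 1867 lower. Across genes, which are not independent replicates, the genotype differences before and after treatment had a Pearson r of 0.744. These differences share no library. In both, 2051 genes were higher in the knock-in, where independent lists would share 592. Another 2113 were lower in both, where they would share 642, and 88 changed direction. Mtdh differed by 0.09 ± 0.04 log2 (edgeR adjusted p = 0.0718), and it passed the threshold without untreated wild-type replicate 2 or treated wild-type replicate 2, at 0.09 and 0.1 log2.

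**Figure D3:**
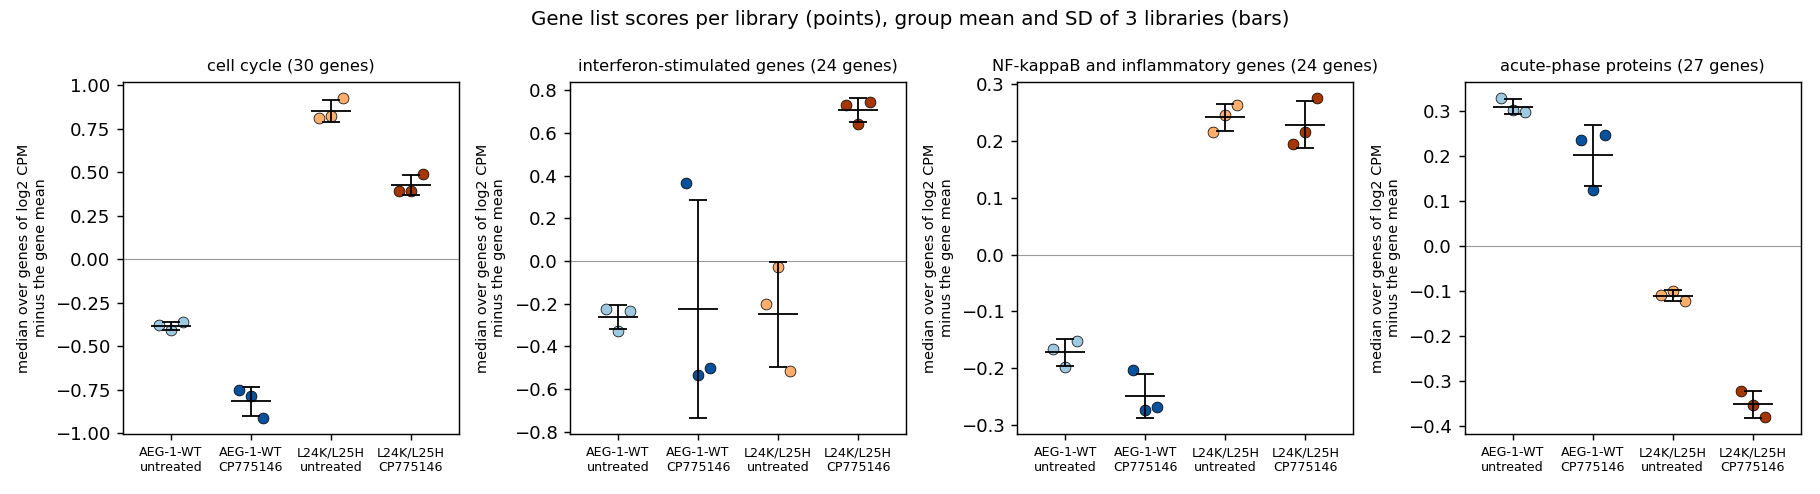
Median over the genes of a list of log2 CPM minus the gene's mean over the 12 libraries, for 4 lists, with points for libraries and bars for the mean ± SD of 3 libraries. Replicate 1 of treated wild type stood at 0.37 for interferon-stimulated genes, and the other libraries of its group at −0.53 and −0.5.

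The fifth comparison asked whether the genotypes answered the agonist differently. For many fatty acid oxidation genes the rise was smaller in the knock-in. Acot1 rose by 6.89 ± 0.07 log2 in wild type and by 5.07 ± 0.06 in the knock-in. Cd36 rose to 700 CPM in wild type and to 1868 CPM in the knock-in, and its response differed by −1.52 ± 0.1 log2 (edgeR adjusted p = 8.12e-07). The response of Creb3l3, a hepatic transcription factor gene that PPAR-alpha controls, differed by −0.86 ± 0.07 log2. For Cyp4a10 and Cyp4a14 the response was larger in the knock-in, by 0.82 ± 0.08 and 0.57 ± 0.06 log2, and for Fabp1 it was larger by 0.84 ± 0.17. The Cyp4a genes are close copies whose reads are hard to assign. Mki67 fell by 1.91 log2 in wild type and by 0.42 log2 in the knock-in, but the cell-cycle list as a whole had no camera call for the interaction.

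The treatment responses of the genotypes, which share no library, had a Pearson r of 0.803 and a Spearman rho of 0.695 across 15664 genes, and 77.6% had the same sign. The slope of the knock-in response on the wild-type response was 0.672. Both genotypes raised 2218 genes, where independent lists would share 642, both lowered 2194, where they would share 667, and 42 moved in opposite directions. The interaction passed the threshold for 1113 genes, 7.1% of those tested, with 435 responses higher and 678 lower in the knock-in, and total-count scaling turned this split to 663 and 519. The 2-fold mark was passed by 34 and 41. Among the 1113 were 352 genes that rose in both and less in the knock-in, 163 that fell in both and less in the knock-in, 44 that rose more and 37 that fell more. A further 330 passed the threshold in wild type alone and 143 in the knock-in alone. Which genotype had more calls with CP775146 depended on the fit, at 7049 in wild type and 5821 in the knock-in with all libraries but 6174 and 6984 with only the compared groups, and 6580 and 7012 with limma voom. Without treated knock-in replicate 1 the interaction count was 716.

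**Figure D4:**
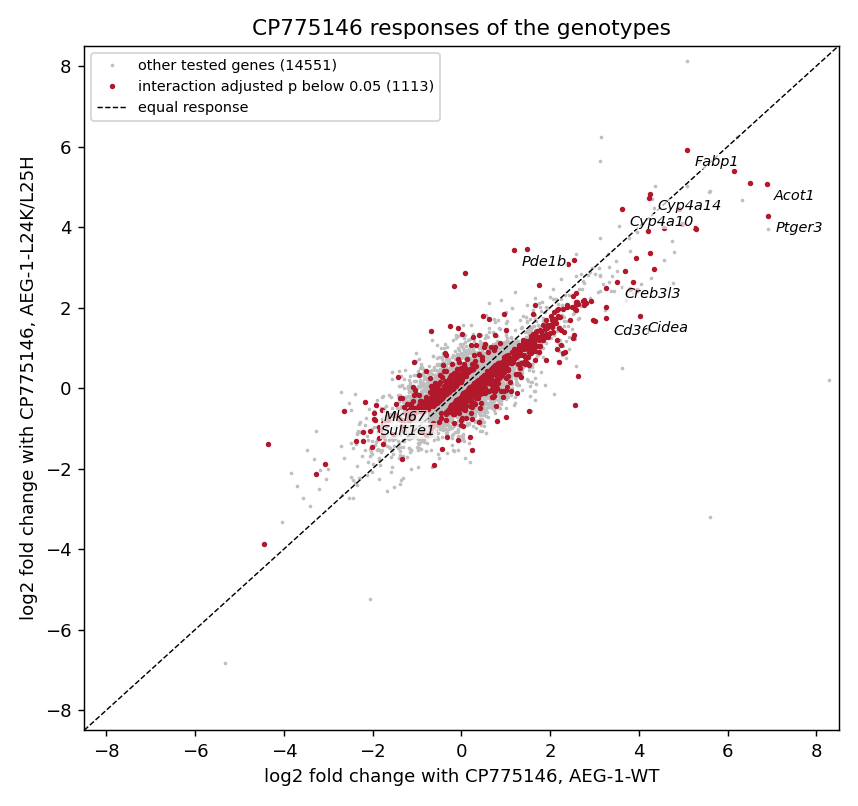
Each point is 1 gene, with its log2 fold change with CP775146 in wild type (horizontal) and in the knock-in (vertical), red for the 1113 genes with an interaction adjusted p below 0.05. The dashed line marks equal responses, the slope across genes was 0.672, and Acot1 and Cd36 lie below the line and Cyp4a10 above it.

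A response is called lower here when the log2 change in the knock-in minus that in wild type was below 0. PPAR-alpha targets had a lower response in the knock-in in 33 of 51 cases and a higher one in 6, with 35 and 7 adjusted over the list alone (median −0.43, limma camera adjusted p = 1.25e-22; adjusted p = 0.0612 with an estimated correlation). Plin2 differed by −0.62 ± 0.05 log2. Mitochondrial beta-oxidation genes had a lower response in 18 of 21 cases, also adjusted over the list alone (median −0.36, limma camera adjusted p = 4.05e-24; adjusted p = 0.0612 with an estimated correlation), with Hadha at −0.48 ± 0.05 log2. Peroxisomal genes had a lower response in 7 of 23 cases and a higher one in 2, with 10 and 3 adjusted over the list alone (median −0.12, limma camera adjusted p = 0.00544; adjusted p = 0.19 with an estimated correlation). Omega-oxidation genes had a higher response in 3 of 9 cases and a lower one in 1, the same adjusted over the list alone (median 0.04, limma camera adjusted p = 0.125). Ketone body genes had a lower response in 3 of 5 cases, and in 4 adjusted over the list alone (median −0.23, limma camera adjusted p = 0.000386; adjusted p = 0.102 with an estimated correlation). Cholesterol synthesis genes had a lower response in 6 of 25 cases and a higher one in 1, with 9 and 1 adjusted over the list alone (median −0.13, limma camera adjusted p = 0.000716; adjusted p = 0.19 with an estimated correlation). Fatty acid and triglyceride synthesis genes had a higher response in 5 of 24 cases and a lower one in 1, with 8 and 1 adjusted over the list alone (median 0.03, limma camera adjusted p = 0.0175; adjusted p = 0.241 with an estimated correlation).

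Targets of the xenobiotic receptors CAR and PXR had a higher response in 8 of 25 cases and a lower one in 3, with 11 and 5 adjusted over the list alone (median 0.13, limma camera adjusted p = 0.017; adjusted p = 0.19 with an estimated correlation). Aldh1a1, a retinal dehydrogenase gene, differed by −0.88 ± 0.07 log2. Acute-phase genes had a lower response in 4 of 27 cases, and in 6 adjusted over the list alone (median −0.12, limma camera adjusted p = 0.00171; adjusted p = 0.19 with an estimated correlation). Cholangiocyte markers had a lower response in 4 of 9 cases, and in 6 adjusted over the list alone (median −0.31, limma camera adjusted p = 0.000116; adjusted p = 0.0606 with an estimated correlation), with Krt19 at −0.99 ± 0.13 log2. Of 24 interferon-stimulated genes none passed with edgeR in either direction, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 14, and DESeq2 and limma voom passed 2 and 15. The list stood apart as a whole (median 0.85, limma camera adjusted p = 2.34e-17; adjusted p = 0.19 with an estimated correlation). Bst2 stood at 163 ± 4.21 and 188 ± 27.3 CPM in wild type and at 167 ± 4.76 and 250 ± 15.8 CPM in the knock-in. In wild type with CP775146 this list rose in 0 and fell in 1 of 24 cases (median 0.07, limma camera adjusted p = 0.915), but without treated wild-type replicate 1 it fell in 11 and rose in 1 (median −0.3, limma camera adjusted p = 0.0138). Of 24 interactions, 22 then passed (median 1.2), Bst2 among them at 0.5 log2. Without treated wild-type replicate 2, the list rose in 3 and fell in 1 of 24 cases in wild type, and 1 interaction passed (median 0.585).

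Large interactions included Pde1b, a cyclic nucleotide phosphodiesterase gene (2.25 ± 0.41 log2, edgeR adjusted p = 0.000538), Tgtp1, an interferon-inducible GTPase gene (1.7 ± 0.31), Oas3, another interferon-inducible gene (1.33 ± 0.26), Sult1e1, the estrogen sulfotransferase gene (1.21 ± 0.14), and Tuba1a (1.21 ± 0.11). On the other side stood Cidea, which encodes a lipid droplet protein (−2.25 ± 0.54), Espn, which encodes the actin bundler espin (−1.42 ± 0.2), Fbp2 (−1.39 ± 0.14), the laminin gene Lamb3 (−1.37 ± 0.13) and H2-Q2, a class I histocompatibility gene (−1.35 ± 0.13), all with an edgeR adjusted p of 0.00911 or lower. Espn stood at 3.53 ± 0.14 and 17.4 ± 3.2 CPM in wild type and at 2.29 ± 0.17 and 4.2 ± 0.43 CPM in the knock-in. Mtdh differed by 0.03 ± 0.06 log2 (edgeR adjusted p = 0.828).

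Several lists had no camera call between the untreated genotypes. Omega-oxidation genes rose in 3 and fell in 6 of 9 cases (median −0.43, limma camera adjusted p = 0.162), ketone body genes rose in 3 and fell in 1 of 5 (median 0.11, limma camera adjusted p = 0.269), and fatty acid and triglyceride synthesis genes rose in 5 and fell in 6 of 24 (median −0.01, limma camera adjusted p = 0.481), all 3 with the same counts adjusted over the list alone. LXR targets rose in 6 and fell in 3 of 14 (median 0.11, limma camera adjusted p = 0.201), bile acid genes rose in 7 and fell in 5 of 18, with 8 rises adjusted over the list alone (median 0.11, limma camera adjusted p = 0.734), and CAR and PXR targets rose in 9 and fell in 11 of 25 (median −0.04, limma camera adjusted p = 0.905). Interferon-stimulated genes rose in 1 of 24 cases, also adjusted over the list alone (median 0.12, limma camera adjusted p = 0.288), and without treated wild-type replicate 1, which is in the same model, 7 rose and 2 fell. Wnt targets rose in 2 and fell in 5 of 13 (median −0.2, limma camera adjusted p = 0.581), although Ccnd1, the cyclin D1 gene, rose from 13.1 ± 1.29 to 37.5 ± 1.21 CPM. Pericentral genes rose in 7 and fell in 8 of 17, with 8 rises adjusted over the list alone (median −0.12, limma camera adjusted p = 0.667). Unfolded protein and integrated stress response genes rose in 9 and fell in 3 of 23, with 10 and 4 adjusted over the list alone (median 0.08, limma camera adjusted p = 0.115).

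Between the untreated genotypes, macrophage markers rose in 3 and fell in 2 of 17 cases (median 0.21, limma camera adjusted p = 0.771), endothelial markers rose in 3 and fell in 5 of 19 (median −0.04, limma camera adjusted p = 0.288), and stellate cell markers rose in 1 and fell in 4 of 16 (median −0.42, limma camera adjusted p = 0.0938), with the same counts adjusted over the list alone. Cd68, a macrophage lysosome gene, fell from 234 ± 22.2 to 151 ± 4.5 CPM, whereas the macrophage genes C1qa and Marco rose. Each of the 2 calls that rose was lost without either of 2 libraries, at 0.465 to 0.503 log2 for C1qa and 0.704 to 0.717 log2 for Marco. Stab2, a sinusoidal endothelial receptor gene, fell from 65.1 ± 4.81 to 33.6 ± 2.54 CPM. None of 20 neutrophil and lymphocyte markers or 7 mesothelial markers had enough counts to be tested. The 13 mitochondrially encoded genes held 0 counts in every library, so the files say nothing about their expression. Of 8 erythroid genes only Alas2 was tested, at 2.45 ± 0.43 and 1.91 ± 0.23 CPM, and of 5 Y-linked and X-inactivation genes only Xist, at 2286 ± 149 and 1634 ± 22.3 CPM. Male-biased liver genes rose in 4 and fell in 4 of 10 cases (median −0.61, limma camera adjusted p = 0.115), and female-biased ones rose in 6 and fell in 3 of 14 (median 0.25, limma camera adjusted p = 0.0751), also adjusted over the list alone.

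Camera called 15 of the 30 tested lists between untreated genotypes, and 5 of these calls held with an estimated correlation: cell cycle, NF-κB, dedifferentiation, cholangiocyte markers, and gluconeogenesis and glycolysis. With CP775146, 12 lists were called in wild type and 17 in the knock-in, of which 9 and 9 held. Between treated genotypes 12 were called and 6 held, and for the interaction 10 were called and none held. Median and camera direction differed in sign for retinoic acid receptor targets with CP775146 in wild type, for cholangiocyte markers in the knock-in, for 6 lists between treated genotypes and for periportal genes in the interaction, none of them called.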

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

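Each result in this part differed between AEG-1-WT (wild type) and AEG-1-L24K/L25H (knock-in) in its response to CP775146, as tested by the interaction. The scaling test of the smaller response, and the single-culture and macrophage tests of the interferon pattern, were chosen only after the result was seen.

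The interaction called 1113 genes. With the libraries split at random into groups of equal size, 60 of 460 splits were drawn. Of these, 1, the real one, reached 1113, and the others gave at most 146. The other splits leave the real interaction in the spread, which lowers their counts. Libraries that may not be separate animals or cultures also cannot show chance differences between preparations, so chance is not excluded. Without treated knock-in replicate 1 the interaction called 716 genes.

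The response was lower in the knock-in, as log2 difference, for Ptger3 (−2.645), Cidea (−2.246), Acot1 (−1.817), Cd36 (−1.525), Espn (−1.42), Fbp2 (−1.392), Lamb3 (−1.374), H2-Q2 (−1.347), Chrna2 (−1.294), Tagln (−0.996), Krt19 (−0.986), Aldh1a1 (−0.885), Creb3l3 (−0.86), Angptl2 (−0.782), Acot3 (−0.754), Plin2 (−0.625), Hadha (−0.48), Pdk4 (−0.445), Angptl4 (−0.438), Lpcat3 (−0.432), Anxa3 (−0.421) and Cpt1a (−0.314). Smaller differences were seen in Krt18 (−0.277), Ahsg (−0.268), Fgb (−0.232), Acacb (−0.22), Osgin1 (−0.218), Acaa2 (−0.211), Tgm2 (−0.208), Slc2a2 (−0.201) and Alb (−0.18). Each value is the log2 change in the knock-in minus that in wild type. A gene that fell more in the knock-in therefore also counts as having a lower response. This was so for Fgb and Slc2a2, and Tagln fell in the knock-in. Ptger3 had 4 counts over the untreated wild-type libraries. Leaving out 1 library ended the call for Ptger3 (8 libraries: untreated wild type 2 and 3, treated wild type 3, untreated knock-in 1, 2 and 3, treated knock-in 1 and 3; −2.85 to −2.08), for Acot3 (untreated wild type 1 and 3, untreated knock-in 1; −0.75 to −0.68), for Tgm2 (untreated wild type 3, treated wild type 3, untreated knock-in 1, treated knock-in 1 and 3; −0.2 to −0.16) and for Fgb (untreated knock-in 2; −0.19).

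The response was higher in the knock-in for Abcc4 (0.346), Ccnd1 (0.429), Icam1 (0.454), Fgd3 (0.473), Acaa1b (0.504), Lgals1 (0.52), Ccl2 (0.53), Sult2a1 (0.532), Cyp1a1 (0.564), Cyp4a14 (0.571), Cps1 (0.618), Slc7a11 (0.781), Cyp4a10 (0.819), Fabp1 (0.838), Tead2 (1.046), Fgfbp1 (1.148), Marcksl1 (1.152), Tuba1a (1.206), Sult1e1 (1.212), Oas3 (1.327), Mki67 (1.491), Tgtp1 (1.704) and Pde1b (2.25). Of these, Ccnd1, Icam1, Fgd3, Ccl2, Sult2a1, Cyp1a1, Cps1, Tead2, Fgfbp1, Marcksl1, Tuba1a, Sult1e1 and Mki67 fell with CP775146 in both genotypes, and by less in the knock-in. Slc7a11 fell in wild type and rose in the knock-in. The call for Sult2a1 ended without untreated wild-type replicate 1 or 3, treated wild-type replicate 1 or 3, or untreated knock-in replicate 2 or 3 (0.44 to 0.54).

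Among lists, the median difference was −0.435 for PPAR-alpha targets, −0.355 for mitochondrial and −0.121 for peroxisomal beta-oxidation, −0.234 for ketone body and −0.127 for cholesterol synthesis, 0.034 for fatty acid and triglyceride synthesis, 0.128 for CAR and PXR targets, −0.123 for acute-phase genes, 0.848 for interferon-stimulated genes and −0.308 for cholangiocyte markers. None of these list calls held with an estimated correlation.

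The smaller response across genes in the knock-in is the first pattern, and PPAR-alpha targets are a part of it. Noise in the wild-type fold changes would lower a slope. The ratio of the response SDs over the 15664 genes with the error removed was 0.826 (0.804 to 0.84 with 1 library left out). The removed error rests on a spread shared by all groups. The coefficient of biological variation was 5.1% and 5.33% in untreated and treated wild type but 2.59% and 2.63% in the knock-in groups. Too little error was thus removed from wild type, which lowers the ratio, so wild-type noise stays open. For PPAR-alpha targets scaling is argued against because the list median was at most −0.399 under 3 scalings (−0.435 with TMM, SE 0.091 over genes). An SE over genes treats the genes of a list as independent. It is not an error over libraries and may be too small. A higher level of these targets before treatment may account for their part of the pattern: the untreated list median was 0.349 log2 higher in the knock-in, a call lost with an estimated correlation (adjusted p = 0.17 with an estimated correlation in limma camera). The untreated libraries enter both the level and the response, which ties them together and weakens this test. With treatment, some of these targets ended higher and others lower in the knock-in than in wild type. A higher level before treatment alone leaves those that ended lower unexplained. An effect of the changed AEG-1 residues on the receptor, and a difference between preparations, stay open as untested.

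The larger response of interferon-stimulated genes in the knock-in is the second. For the rise with CP775146 within the knock-in, an increase in macrophages is argued against, since their markers had a median change of −0.456 log2 (SE 0.119 over genes). Whether macrophages already present were its source was not tested. For the difference between treated genotypes, more macrophages in the knock-in stay open. The marker median was 0.327 log2 higher there (SE 0.187 over genes), with 5 markers higher and 2 lower of 17. Adjusted over the list alone, 1 was higher and 2 lower. The limma camera adjusted p was 0.836, and the spread was too wide to decide. Differences between single cultures stay open too, because with 1 library left out the list median of the interaction fell as low as 0.585 (without treated wild-type replicate 2), less than 2 SE over libraries (SE 0.461). Treated wild-type replicate 1, which lay 0.852 log2 above the mean of the other libraries of its group, is not the source, since without it the median was 1.2. A genotype effect stays open as untested against preparation.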

How the results depend on the processing

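Thinning the libraries was the only test in this part chosen after the result was seen. Of named genes under alternatives other than leaving out a library, 4020 results kept direction and side of the threshold, 36 lost and 18 gained the call. Of gene lists 556 kept them, 39 lost and 5 gained the call. With 1 library left out, 7998 gene results kept them, 135 lost and 15 gained the call, and for lists 1783, 6 and 10. No named gene reversed, and 1 list did. The kept list results include many lists without a call in the main fit, and most of the 39 losses came from the estimated correlation. With it, 5 of 15 list calls held between untreated genotypes, and 9 of 12 and 9 of 17 with CP775146 in wild type and knock-in. Between treated genotypes 6 of 12 held, and for the interaction 0 of 10.

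Requiring a 2-fold change gave 754 genes between untreated genotypes, 1015 and 651 with CP775146 in wild type and knock-in, 911 between treated genotypes and 75 for the interaction, by construction. The response r and slope were 0.918 and 0.783 with the stricter filter and 0.87 and 0.723 for genes past the threshold in either genotype, both with fewer genes. The calls for PPAR-alpha targets between untreated genotypes (adjusted p = 0.17 with an estimated correlation in limma camera, median 0.349) and in the interaction (adjusted p = 0.0612, median −0.435) were lost; the estimate allows for genes that vary together.

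Counts in the order untreated genotypes, wild type with CP775146, knock-in with CP775146, treated genotypes and interaction were 5810, 7062, 5811, 6680 and 1113 with RLE, 5135, 6355, 5130, 5954 and 1054 with DESeq2, 6130, 6580, 7012, 6657 and 1332 with voom, 5724, 6962, 5732, 6571 and 1343 without a filter, 4870, 5906, 5074, 5557 and 1130 with the stricter one, and 5652, 6917, 5594, 6443 and 1049 after thinning. With the replicate number as a replicate block they were 5775, 7023, 5761, 6638 and 1130. With a replicate block of its own for each number within a genotype, CP775146 gave 6852 genes in wild type and 5570 in the knock-in, and the interaction 1010, of which 934 were among the 1113. The labels do not say that numbers pair cultures. Residuals had r over 0.1 in 6 of 18 pairs with equal numbers (−0.212 to 0.32, against −0.25 to 0.336 for different numbers), so the numbers were not taken as pairs across the design. Between treated wild type and treated knock-in, equal numbers had r of 0.216, 0.167 and 0.224 and different numbers at most 0.002. Between untreated and treated wild type, however, unequal numbers stood out, at 0.336 (1 with 2) and 0.202 (2 with 1). The match of equal numbers is therefore no sign of pairing, which stays open. The replicate block changed no call of a named gene or list between treated genotypes.

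Leaving out each library gave 4957 to 6030, 6245 to 6971, 4807 to 6091, 5757 to 6861 and 716 (without treated knock-in replicate 1) to 1471 (without untreated wild-type replicate 3) genes, r of 0.775 to 0.799 and slopes of 0.622 to 0.683. The interferon list with CP775146 in wild type, at a median of 0.068, reversed without treated wild-type replicate 1 (median −0.301, limma camera adjusted p = 0.0138), and the highest adjusted p was 0.942. The PPAR-alpha list had limma camera adjusted p-values of 4.6e-09 to 9.44e-08 between untreated and 0.529 to 0.976 between treated genotypes, 2.44e-73 to 2.66e-66 and 6.18e-89 to 1.83e-76 with CP775146, and 5.83e-24 to 9.74e-20 for the interaction. Where no cause is given, it was not tested. At this depth, genes under 0.111 CPM could not be followed.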

Other observations

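The cholangiocyte test of the cell-cycle pattern was chosen only after the result was seen. The lists of glucocorticoid receptor, aryl hydrocarbon receptor and fetal genes were written after gene values had been seen, and Cyp1a1, which lies outside the naming rule, was picked after its values were seen.

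Fgf21, a fasting hormone gene, rose from 1.47 to 7.5 CPM in wild type and from 2.93 to 14.6 CPM in the knock-in. Angptl4, which encodes an inhibitor of lipoprotein lipase, rose by 1.72 ± 0.05 and 1.28 ± 0.05 log2. Cyp2b10, a xenobiotic cytochrome P450 gene, fell from 1890 to 1010 CPM in wild type and from 1180 to 604 CPM in the knock-in. Ppara itself rose by 0.54 ± 0.05 log2 in wild type and 0.36 ± 0.05 log2 in the knock-in.

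Between untreated genotypes, Hsd17b13, which encodes a lipid droplet enzyme, was lower in the knock-in, at 628 against 1076 CPM. Krt18, a keratin gene of hepatocytes, was higher, at 3287 against 1900 CPM, as was Osgin1, an oxidative stress gene (0.87 ± 0.04 log2). Cdkn1a, which encodes the cell cycle inhibitor p21, was lower (−0.4 ± 0.04 log2), and so was Sesn1, another p53 target (−1.05 ± 0.06 log2).

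Higher cell-cycle genes in the untreated knock-in are the third pattern weighed. A joint rise of stellate, macrophage and endothelial cells is argued against, since stellate markers had a median of −0.416 log2 (SE 0.138 over genes). Macrophage markers had 0.209 (SE 0.128 over genes) and endothelial markers −0.042 (SE 0.197 over genes). More of either of these cell types alone stays open. Scaling (cell-cycle list median at least 1.387 under 3 scalings) and depth (1.371 after thinning) are argued against too. Cholangiocytes may contribute, since their list median was 0.584 log2, but 4 of these markers are also dedifferentiation genes that hepatocytes express in culture, and the 2 sources cannot be told apart here. A genotype effect on proliferation stays open as untested against preparation and animals.

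Splits of the 6 libraries of a 2-group comparison number 10, too few for a share under 0.05. With edgeR on the compared groups alone, the real split gave 5750 genes between untreated genotypes and 6627 between treated genotypes. It gave 6174 genes with CP775146 in wild type and 6984 in the knock-in. The highest of the other splits gave 0 in each, and 1 split, the real one, reached the real value. Every other split mixes the compared groups, which puts the real differences into the spread and lowers its count. These zeros therefore do not exclude chance.

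Of 14 glucocorticoid receptor targets, chosen after Tat and other genes were seen to fall, 8 fell and 2 rose with CP775146 in wild type (median −0.295, limma camera adjusted p = 0.00911) and 10 fell and 2 rose in the knock-in (median −0.297, limma camera adjusted p = 0.000759); adjusted p = 0.0407 and 0.0138 with an estimated correlation. The list was as much lower between genotypes: 10 were lower and 3 higher in the untreated knock-in (median −0.291, limma camera adjusted p = 0.00117), and 9 and 2 in the treated one (median −0.303, limma camera adjusted p = 0.00226); adjusted p = 0.0164 and 0.0215 with an estimated correlation. Lower glucocorticoid receptor activity with CP775146 is a candidate explanation that this test on the same data leaves as a hypothesis, and the list is not specific to CP775146. Of 5 tested aryl hydrocarbon receptor targets, 3 and 2 fell, and the higher of the medians was −0.139 log2 (limma camera adjusted p = 0.452 and 0.357). Of 13 tested fetal and imprinted genes, 3 rose and 4 fell between untreated genotypes (median 0.035, limma camera adjusted p = 0.723, camera direction down). Within 10 Mb of Mtdh, 2 of 54 tested genes differed at least 2-fold between untreated genotypes, against 752 of 15610 elsewhere, an odds ratio of 0.76 (95% interval 0.0895 to 2.9, Fisher's exact p = 1).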
